A study of Pimephales promelas and Danio rerio with 59 samples.

How the data were processed

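Gene expression was measured in whole fry of 2 fish species after 96 h in RDX, on 59 arrays: 24 of zebrafish, and 35 of fathead minnow from 19 fish replicates. Per the labels, each replicate was a pool of 10 fry from its own beaker, the water was renewed at 48 h, and Cy3-labelled RNA was made from 0.4 ug of total RNA. Scanner output with spots was used from 58 arrays. The text deposited for 1 zebrafish array of 0.9 mg/L held no spots, so this group has 3 replicates. Concentrations are the nominal ones of the sample titles. In the treatment protocol 1.9 mg/L reads 1.8, 7.5 mg/L reads 7.0 and 15 mg/L reads 13.8.

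The scanner output gives a processed signal intensity per spot, made per the file headers with Agilent Feature Extraction 9.5.1.1, on a linear scale and without scaling between arrays. The sample text deposited in place of the array without spots names another image program, so the upstream steps are stated in 2 ways in the sources used here. The value table of the series holds log2 values that the authors made, for zebrafish per the text deposited with that array, by a shift to the 75th percentile of each array and a baseline at the median of all samples of each probe. For fathead minnow these steps are not given in the sources used here, and its values are centred at each probe's median in the same way. Its columns have medians from -0.0847 to 0.0850 in zebrafish and from -0.121 to 0.270 in fathead minnow, and the lowest correlation of a column with its own scanner values was 0.994 and 0.995. Its log2 scale, its centring at each probe's median and its direction were checked against the scanner values, and the exact order of its upstream steps is not given in the sources used here.

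The zebrafish array has 45220 spots, of which 43803 are not control spots, for 43603 probes. The fathead minnow array has 15744 spots and 15208 probes. The base 2 logarithm of the processed signal was taken, the 75th percentile of the array was subtracted, control spots and spots with an outlier mark were left out, and duplicate spots of a probe were averaged. A probe was tested if it was well above background in at least 3 samples of at least 1 group and had at least 2 usable values in every group, which left 32221 zebrafish and 12335 fathead minnow probes. The fathead minnow replicates had been hybridised in a run at a detector setting of 420 (19 arrays) and a run at 440 (16 arrays). The difference between runs was estimated from the 16 replicates in both and subtracted, and the arrays of a replicate were averaged. The correlation of a replicate's deviations between the runs had a median of 0.415 (0.115 to 0.806), against -0.032 for different replicates. Of the 16 arrays of the 420 run 12 matched their own replicate best in the 440 run, and 0.9 mg/L replicate 1 (0.211), 7.5 mg/L replicates 1 (0.156) and 3 (0.115) and 15 mg/L replicate 3 (0.328) did not, but were averaged as well. No 2 arrays held identical values.

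Each concentration was compared with the control of its species in 1 linear model per species with limma 3.58.1 in R 4.3.3, with an intensity trend in the prior variance. Adjusted p-values are by Benjamini and Hochberg over all tested probes of a comparison, and a probe is called at an adjusted p under 0.05. The trend is the slope on the base 2 logarithm of the concentration plus 1 mg/L. Where a group was not well above background, the fold is given as a bound against the background level. This bound holds for the processing above and not for other background corrections. On simulated data with 100 changed probes of each size the comparison at 15 mg/L recovered 65% of zebrafish changes of 1 and 96% of changes of 2 in log2, with 15 unchanged probes called. For fathead minnow these were 69% and 93%, with 5 unchanged probes called. The trend recovered 73% and 98% of slopes of 0.25 and 0.5 in zebrafish (9 unchanged probes called). In fathead minnow these were 78% and 95% (6 unchanged probes called). A list of 23 zebrafish genes raised by 0.5 passed while 0 of the others did. The simulations held no slide differences and no correlation between genes, whereas correlations estimated for lists in the data reached 0.377. They therefore do not show how often unchanged lists or probes pass in the data.

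In zebrafish 23 gene lists for tissues and processes were tested over 5320 genes with a symbol, with the brightest probe of each gene and marked spots kept. The test was camera of limma with a preset correlation of 0.01, next to a correlation estimated per list and to fry. The lists at concentrations other than 15 mg/L are descriptive. The lists cover GABA and glutamate signalling, neurons, glia, activity-induced early genes, antioxidants, heat shock and ER stress, xenobiotic metabolism, p53 and apoptosis, cell cycle, erythroid cells, liver secreted proteins, exocrine pancreas, muscle, photoreceptors, lens, bone and matrix, sterol synthesis, fasting, the respiratory chain, ribosomal proteins, immunity and epidermis. Overlaps between comparisons that share controls were set against independent lists, simulated groups without effect and split controls.

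Genes are named by a rule set, like the comparisons, lists and alternatives, before the data were examined. It takes 1 probe per gene, the brightest, and only names of the form of a gene symbol. The 10 largest changes each way past the threshold are named at 15 mg/L, 5 at 7.5 mg/L, 3 at lower concentrations and 5 slopes of the trend, up to 4 members per list, and cyp1a, hmox1 and fos everywhere because of what the compound does. Some items that the rule names are not reported here. Where fewer genes passed, all that passed are named with the 3 smallest p-values that did not pass. The fathead minnow array gives no symbols and 0 of its probes matched the reference table, so its probes are named by identifier, and gene lists and a comparison of the species were not run.

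The alternatives were quantile normalisation, normexp background correction with an offset of 50, no filter on dim probes, the deposited value table, blocks for slide and for replicate number, a fit of only the groups compared, either fathead minnow run alone or all its arrays with run as a covariate, and leaving out each replicate in turn. Arrays came from 6 zebrafish slides and 7 fathead minnow slides, each scanned on a single day, so the slide block covers the day. An analogue of the study's own test across all groups, a moderated F of limma over all measured probes, called 3934 of 42448 probes in zebrafish and 177 of 14305 in fathead minnow. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.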

Results

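RDX is a nitramine explosive that blocks GABA-A receptors and causes seizures in vertebrates. Fry of zebrafish and fathead minnow, 3 days old at the start, were kept for 96 h in water with or without RDX, and RNA from pools of 10 whole fish was hybridised to 1-colour Agilent arrays of 1 design per species. Each replicate was a separate beaker. The zebrafish arrays covered a control and 5 RDX concentrations (15, 7.5, 3.8, 1.9 and 0.9 mg/L), with 4 replicates per group except 0.9 mg/L, where 3 were used. The fathead minnow arrays covered a control with 3 replicates and the same concentrations except 3.8 mg/L, with 4 replicates each. Of these 19 replicates 16 were hybridised in both of 2 runs. The median processed signal of an array lay between 34.5 and 57.9 in zebrafish and between 231 and 644 in fathead minnow, and 67.2% to 78.9% and 74.9% to 95.3% of spots were well above background. The number of arrays limits the precision of every value. Changes are given as log2 differences from the control of the same species with their standard error (SE), for 4 exposed and 4 control zebrafish replicates unless another n is given.

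The first question was which transcripts of zebrafish fry differ from the control at 15 mg/L RDX, the highest concentration arrayed. The transcript of hsp47, a chaperone of collagen in the endoplasmic reticulum, rose by 3.46 ± 0.33 (adjusted p = 2.67e-07). The Hsp40 family gene dnaja1l rose by 2.29 ± 0.22 (adjusted p = 2.67e-07) and hspa4l, of the Hsp70 superfamily, by 1.90 ± 0.29 (adjusted p = 6.69e-05). The transcript of fkbp5, a co-chaperone of the glucocorticoid receptor, rose by 2.60 ± 0.40 (adjusted p = 0.000127, n = 2 exposed replicates with a usable spot). The immediate early gene fos, which neurons switch on when they fire, rose by 2.28 ± 0.50 (adjusted p = 0.00194), and all 5 of its probes passed. Signalling genes among the 10 largest rises were socs3, a feedback inhibitor of cytokine signalling, at 2.14 ± 0.22 (adjusted p = 7.27e-07), and hamp1, which encodes the iron hormone hepcidin, at 1.85 ± 0.26 (adjusted p = 2.35e-05). Further rises were ndrg1l at 2.05 ± 0.17 (adjusted p = 1.2e-07) and the RNA-binding protein gene rbmx at 1.81 ± 0.15 (adjusted p = 7.48e-08). The sialyltransferase gene siat6l was not well above background in the controls and was at least 1.61-fold higher in the exposed fish (adjusted p = 0.0095). That bound holds for the main processing only, since with normexp correction its log2 change was 0.17. Every exposed replicate measured lay above the control mean for each of these 10 genes.

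Among the 10 largest falls at 15 mg/L, the cytochrome P450 gene cyp2j28 changed by -2.84 ± 0.24 (adjusted p = 1.2e-07) and the glucuronosyltransferase gene ugt1ab by -2.13 ± 0.26 (adjusted p = 5.58e-06). Of the enzymes of lipid breakdown, the fatty acid amide hydrolase gene faah2b changed by -1.90 ± 0.27 (adjusted p = 2.29e-05) and the ceramidase gene asah2 by -1.86 ± 0.25 (adjusted p = 1.17e-05). The gene gatm, which encodes the first enzyme of creatine synthesis, changed by -1.82 ± 0.20 (adjusted p = 3.74e-06, n = 3 controls), and the aldo-keto reductase gene akr1a1a by -1.76 ± 0.37 (adjusted p = 0.00141). The circadian repressor per4 changed by -2.15 ± 0.20 (adjusted p = 2.29e-07). The transcription factor genes irf1 and irf11 were at -1.99 ± 0.42 (adjusted p = 0.00151) and -1.92 ± 0.35 (adjusted p = 0.00041). The immunoproteasome gene psmb8 was lower (adjusted p = 0.017), but it was well above background in only 1 of the 4 exposed replicates and in 3 controls, so no size is given. All 4 exposed replicates lay below the control mean for each of these 10 genes. Of the genes asked of every comparison, hmox1, a heme oxygenase induced by oxidative stress, rose by 0.79 ± 0.19 (adjusted p = 0.00379). The value of cyp1a, the classical target of the aryl hydrocarbon receptor, at -0.60 ± 0.24 (adjusted p = 0.0912, n = 3 controls), did not pass.

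Across the array, limma called 6835 of 32221 probes at 15 mg/L, 3637 up and 3198 down, and 957 of them changed at least 2-fold, 365 up and 592 down. With slide as a block 3069 were called (1295 up, 1774 down), 2838 of them among the 6835. In that fit fos (2.08, adjusted p = 0.108) and akr1a1a (-1.66, adjusted p = 0.0796) did not pass. Neither did siat6l (adjusted p = 0.0707) and psmb8 (adjusted p = 0.177). Normexp background correction called 2807 (1318 up, 1489 down), also ended the calls of siat6l, psmb8 and akr1a1a, and moved dnaja1l to 1.23, ugt1ab to -1.25, irf1 to -1.16 and faah2b to -1.14. The gene psmb8 lost its call without exposed replicate 1 (adjusted p = 0.0542) or 2 (adjusted p = 0.0692) or control replicate 3 (adjusted p = 0.0831).

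**Figure D1:**
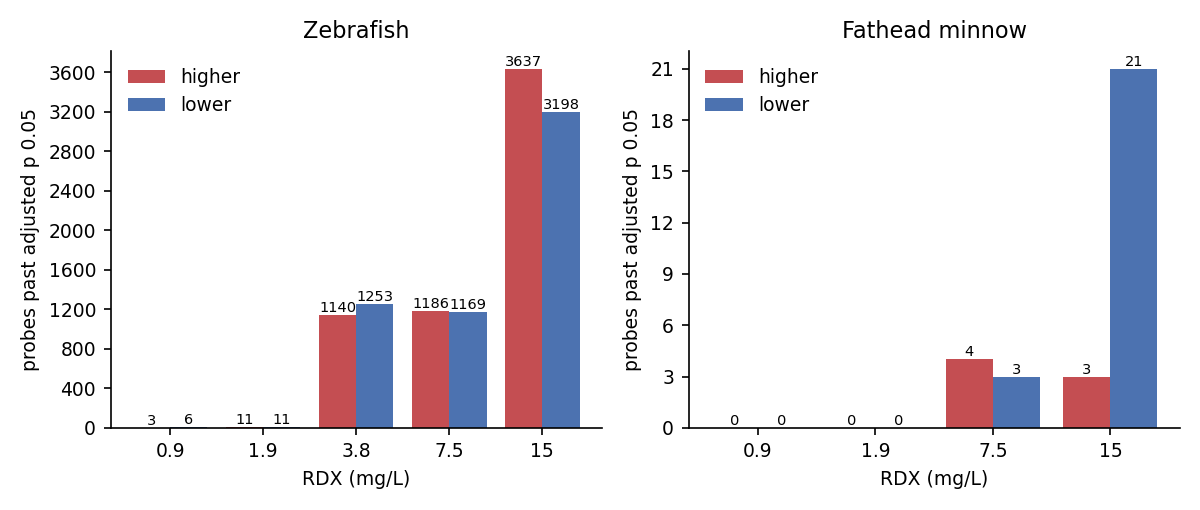
Number of probes past an adjusted p of 0.05 against the control (y axis, linear) at each RDX concentration (x axis, mg/L) in each species, higher and lower shown as separate bars. In zebrafish 22 probes were called at 1.9 mg/L and 2393 at 3.8 mg/L, and in fathead minnow at most 24 at any concentration.

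Gene lists fixed beforehand were tested at 15 mg/L with camera, and 8 of 23 passed with a preset correlation, 3 up and 5 down. None passed with a correlation estimated per list, where the lowest adjusted p was 0.17. Activity-induced early genes were higher (camera adjusted p = 3.58e-06; adjusted p = 0.17 with an estimated correlation). Of 19 measured members 11 rose, 0 fell and 8 did not pass, and 13 rose adjusted over the list alone. Next to fos these were, for example, the transcription factor genes jun at 1.23 ± 0.15 and atf3 at 1.66 ± 0.25, and bdnf, a growth factor of neurons, at 0.66 ± 0.09. In the heat shock and ER stress list 8 of 21 rose and 0 fell (camera adjusted p = 0.00142; adjusted p = 0.403 with an estimated correlation), and 10 rose adjusted over the list alone. Examples are the small heat shock protein gene hspb11 at 1.75 ± 0.25, the Hsp40 gene dnajb1 at 1.35 ± 0.14 and hspd1, the mitochondrial chaperonin, at 0.93 ± 0.21. The p53 and apoptosis list had 10 of 28 members up and 0 down, and 10 up adjusted over the list alone (camera adjusted p = 0.00285; adjusted p = 0.258 with an estimated correlation). It held the pro-apoptotic bax at 0.85 ± 0.11 and bbc3 at 0.38 ± 0.08, and the anti-apoptotic mcl1b at 1.46 ± 0.15. On the only slide that held both groups, 1 array each, the median change of the heat shock list was 0.03, against 0.39 over all arrays. The control there, replicate 4, had a mean level over this list of 0.137, against -0.06 to -0.0375 for the other controls. The exposed array there was at 0.369.

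Lists of liver, skeleton, gut and dividing cells were lower at 15 mg/L. Of 25 genes for proteins secreted by the liver 17 fell and 1 rose, with a median of -0.69 (camera adjusted p = 3.58e-06; adjusted p = 0.17 with an estimated correlation), and 18 fell and 1 rose adjusted over the list alone. Among them were the complement gene c9 at -1.32 ± 0.16, fabp10, the fatty acid binding protein of the liver, at -1.28 ± 0.16, and prothrombin (f2) at -0.97 ± 0.11. In the bone, cartilage and matrix list 14 of 25 fell and 2 rose (camera adjusted p = 0.000881; adjusted p = 0.17 with an estimated correlation), with 16 down and 2 up adjusted over the list alone. The collagen genes col1a1 and col1a2 fell by 1.58 ± 0.18 and 1.51 ± 0.16, the cartilage matrix gene matn4 fell by 1.32 ± 0.13, and lox, which crosslinks collagen, rose by 1.39 ± 0.14. Of 42 cell cycle genes 16 fell and 3 rose (camera adjusted p = 0.00112; adjusted p = 0.396 with an estimated correlation), and 20 fell and 4 rose adjusted over the list alone. Among them were the replication helicase genes mcm3 at -1.63 ± 0.15, mcm5 at -1.42 ± 0.18 and mcm2 at -1.18 ± 0.16. In the exocrine pancreas and digestion list 7 of 14 fell and 0 rose, and the same number fell adjusted over the list alone (camera adjusted p = 0.00229; adjusted p = 0.403 with an estimated correlation). The gut protease gene mep1a.2 fell by 1.44 ± 0.17 and the carboxypeptidase gene cpa1 by 0.82 ± 0.19. Of 22 genes of xenobiotic metabolism 9 fell and 3 rose, and 13 fell and 3 rose adjusted over the list alone (camera adjusted p = 0.0306; adjusted p = 0.396 with an estimated correlation). This list did not pass without exposed replicate 1 (adjusted p = 0.0565) or control replicate 4 (adjusted p = 0.0516). The glutathione transferase gene gstm fell by 1.32 ± 0.13 and cyp4v2 by 1.49 ± 0.27, and the sulfotransferase gene sult2st1 rose by 1.19 ± 0.12. With slide as a block all 8 lists passed, with adjusted p from 3.42e-06 for the liver list to 0.0207 for the heat shock list, and on the slide with both groups the liver median was -0.87.

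**Figure D2:**
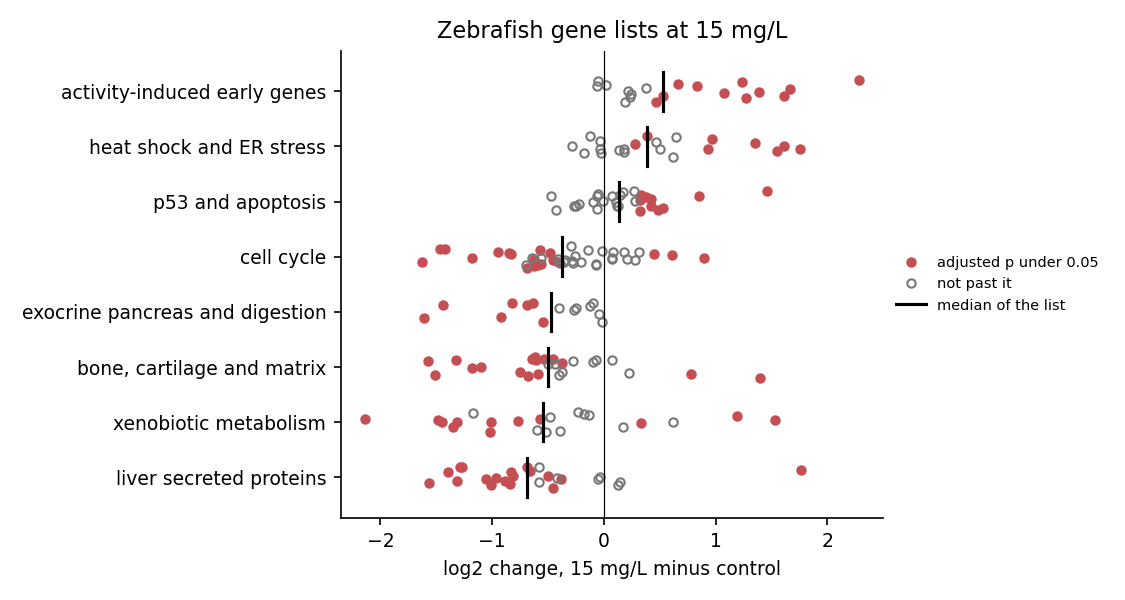
Each point is a gene of a list that passed camera in zebrafish at 15 mg/L, placed by its log2 change against the control (x axis) within its list (y axis, points spread at random for display), filled where its own adjusted p is under 0.05, with a black bar at the list median. Early genes, heat shock and p53 lists have medians above 0 and the other 5 lists medians below 0.

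The nervous system lists did not pass camera at 15 mg/L. Of the 48 names in the GABA list 7 were tested, and of the 51 in the glutamate list 12. Their results therefore speak only for the tested genes, in RNA of whole fry. Of 7 GABA signalling genes measured, 3 rose and 0 fell, with 3 up and 1 down adjusted over the list alone (adjusted p = 0.316). Of these, gabarapl2 was at 0.30 ± 0.09 and lost its call without control replicate 1 (0.26, adjusted p = 0.0527). The others were its relative gabarap at 0.30 ± 0.10 and the GABA-B receptor gene gabbr1 at 0.43 ± 0.14. Without exposed replicate 3 gabarap had an adjusted p of 0.135 and gabbr1 of 0.072, and without control replicate 1 these were 0.153 and 0.0647. The call of gabarap also ended without exposed replicate 1 or 2 or control replicate 2 (adjusted p = 0.0552, 0.0716 and 0.0561). That of gabbr1 ended without exposed replicate 2 or 4 or control replicate 3 or 4 (adjusted p = 0.12, 0.0821, 0.108 and 0.0674). In the glutamate list 1 of 12 fell and 0 rose, with 3 up and 3 down adjusted over the list alone (adjusted p = 0.722), and that gene was slc1a2, a glial glutamate transporter, at -0.49 ± 0.11. Of 21 neuron markers 2 rose and 2 fell (adjusted p = 0.722), with 2 up and 1 down adjusted over the list alone. The neuronal sodium pump gene atp1a3b rose by 0.81 ± 0.20 (0.52 without control replicate 3), and its paralog atp1a3a, at 0.56 ± 0.16, lost its call without exposed replicate 4 (0.48, adjusted p = 0.0548). The tubulin gene tubb5 fell by 1.05 ± 0.11. In the glia and myelin list 3 of 12 fell, also adjusted over the list alone (adjusted p = 0.256), including cldn19 at -1.25 ± 0.15 and the radial glia gene fabp7a at -0.58 ± 0.10. The test fry passed the glia list as lower (fry adjusted p = 0.000571), and not the GABA (0.115), glutamate (0.716) and neuron (0.763) lists.

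Markers of other tissues and functions also did not pass camera as lists at 15 mg/L. The antioxidant list (2 up, 8 down of 22; 2 and 8 adjusted over the list alone; adjusted p = 0.256) held gclm, of glutathione synthesis, at 0.96 ± 0.11 and catalase (cat) at -0.55 ± 0.13. The immune list (7 up, 8 down of 43; 8 and 12 adjusted over the list alone; adjusted p = 0.729) held nfkbiab and nfkbiaa, inhibitors of NF-kB, at 0.97 ± 0.12 and 0.87 ± 0.11 next to socs3. The fasting and fatty acid oxidation list (1 up, 5 down of 17; 3 and 8 adjusted over the list alone; adjusted p = 0.0955) held the peroxisomal oxidation gene ehhadh at -1.26 ± 0.11. Its gene igfbp1, which fasting induces, was at 0.79 ± 0.11 (n = 3 exposed). Photoreceptor genes (2 up, 6 down of 22; 3 and 6 adjusted over the list alone; adjusted p = 0.322) included the cone genes pde6c at -1.22 ± 0.12 (n = 3 exposed) and grk7a at -1.21 ± 0.20. Epidermis (2 up, 7 down of 23; 2 and 8 adjusted over the list alone; adjusted p = 0.0992) included the desmosome gene dspa at -1.03 ± 0.10. Muscle (1 up, 6 down of 30, also adjusted over the list alone; adjusted p = 0.315) included smyhc1, a slow myosin, at 0.75 ± 0.15 and parvalbumin pvalb4 at -0.88 ± 0.14. Of 23 erythroid genes 1 rose and 4 fell (1 and 6 adjusted over the list alone; adjusted p = 0.246). Sterol synthesis had 1 up and 3 down of 17 (2 and 4 adjusted over the list alone; adjusted p = 0.316), with hmgcrb, the rate-limiting enzyme, at 0.63 ± 0.12. In the lens list 2 of 23 rose and 1 fell, the same counts as adjusted over the list alone (adjusted p = 0.31). The respiratory chain had 1 up and 4 down of 29, also adjusted over the list alone (adjusted p = 0.256). Of 63 ribosomal protein genes 2 rose and 0 fell, and 0 passed adjusted over the list alone (adjusted p = 0.99). With an estimated correlation the adjusted p of the 15 lists not passing ran from 0.258 for fasting to 0.997 for ribosomal proteins. With slide as a block the muscle list (adjusted p = 0.0355) and the epidermis list (adjusted p = 0.00292) passed as lower. The test fry passed the fasting (fry adjusted p = 3.84e-06), erythroid (0.00124) and epidermis (0.00237) lists as lower. It also passed the sterol (0.0068), antioxidant (0.0115) and photoreceptor (0.0165) lists as lower. The muscle, lens, respiratory chain, ribosomal and immune lists did not pass fry.

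At 7.5 mg/L the fry had raised transcripts of fkbp5, at 2.39 ± 0.36 (adjusted p = 0.000535, n = 3 exposed), hsp47 at 2.22 ± 0.33 (adjusted p = 0.000337) and ndrg1l at 1.61 ± 0.17 (adjusted p = 1.86e-05). Among the 5 largest rises were also the angiotensinogen gene agt at 1.51 ± 0.22 (adjusted p = 0.000332) and hamp1 at 1.48 ± 0.26 (adjusted p = 0.00137). The largest falls were abcc2, an efflux transporter of conjugates, at -2.23 ± 0.59 (adjusted p = 0.0212) and nr1d1, a circadian repressor, at -1.70 ± 0.24 (adjusted p = 0.000224). Next came cyp2j28 at -1.63 ± 0.24 (adjusted p = 0.000353), irf11 at -1.60 ± 0.35 (adjusted p = 0.00688) and akr1a1a at -1.58 ± 0.37 (adjusted p = 0.0102). The values of fos at 1.35 ± 0.50 (adjusted p = 0.106), cyp1a at -0.44 ± 0.24 (adjusted p = 0.337, n = 3 controls) and hmox1 at 0.34 ± 0.19 (adjusted p = 0.321) did not pass. Without exposed replicate 3 fos was at 0.52, and without exposed replicate 4 cyp1a was at -0.27. Of the lists 7 passed camera, 2 up and 5 down. The liver list (1 up, 11 down; 1 and 17 adjusted over the list alone; camera adjusted p = 1.4e-07; adjusted p = 0.0994 with an estimated correlation) was lower, with fabp10 at -0.97 ± 0.16. Bone and matrix genes were lower (2 up, 6 down; 2 and 12 adjusted over the list alone; camera adjusted p = 0.000806; adjusted p = 0.208 with an estimated correlation), with col1a2 at -0.87 ± 0.16. Early genes were higher (3 up, 0 down; 5 and 0 adjusted over the list alone; camera adjusted p = 0.0099; adjusted p = 0.541 with an estimated correlation), with jun at 0.84 ± 0.15. Their mean change of 0.383 was 0.215 without exposed replicate 3 (camera adjusted p = 0.0462). The p53 and apoptosis list was higher (3 up, 0 down, also adjusted over the list alone; camera adjusted p = 0.0245; adjusted p = 0.518 with an estimated correlation). Xenobiotic metabolism was lower (1 up, 7 down; 4 and 10 adjusted over the list alone; camera adjusted p = 0.0099; adjusted p = 0.351 with an estimated correlation), with ugt1ab at -1.36 ± 0.26. Cell cycle genes (3 up, 8 down; 4 and 10 adjusted over the list alone) and the exocrine pancreas list (0 up, 3 down; 0 and 4 adjusted over the list alone) were lower too, each with a camera adjusted p = 0.0108 (adjusted p = 0.562 with an estimated correlation). The heat shock list, with 2 of 21 up and 4 up adjusted over the list alone, did not pass (camera adjusted p = 0.0987). The p53 list did not pass without exposed replicate 3 (adjusted p = 0.0731) or control replicate 2 (adjusted p = 0.0592), and the exocrine pancreas list not without control replicate 2 (adjusted p = 0.107). The slide block ended the call of the p53 list (adjusted p = 0.0992), and with it the lens list passed as higher (adjusted p = 0.031) and the epidermis list as lower (adjusted p = 0.00329). Without the block the lens and epidermis lists did not pass, at a camera adjusted p of 0.058 and 0.319. With an estimated correlation these were 0.562 and 0.672.

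In all, 2355 of 32221 probes were called at 7.5 mg/L, 1186 up and 1169 down, and 238 of them changed at least 2-fold. No slide held both this group and controls. With slide as a fixed block 158 probes were called (56 up, 102 down), 143 of them among the 2355. In that fit fkbp5 (2.86, adjusted p = 0.166), abcc2 (-2.83, adjusted p = 0.326) and nr1d1 (-1.87, adjusted p = 0.0544) did not pass. Neither did irf11 (-2.02, adjusted p = 0.142) and akr1a1a (-1.41, adjusted p = 0.453). Normexp correction put the median of all probes at 0.21 and called 823 (287 up, 536 down). It ended the call of akr1a1a (-0.18, adjusted p = 0.627) and moved abcc2 to -1.25, and without replicate 4 of this group 1468 probes were called. The gene abcc2 lost its call without that replicate (-1.46, adjusted p = 0.0756) or control replicate 3 (-2.13, adjusted p = 0.054).

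The largest rise at 3.8 mg/L was that of the Hsp90 gene hsp90a.1, by 2.34 ± 0.38 (adjusted p = 0.000636), before hspa4l by 1.94 ± 0.29 (adjusted p = 0.000356) and hspb11 by 1.91 ± 0.25 (adjusted p = 0.000107). The largest falls were irf11 at -1.81 ± 0.35 (adjusted p = 0.00272) and the parvalbumin gene pvalb5, a calcium buffer, at -1.68 ± 0.14 (adjusted p = 1.04e-06). Next to them stood omp, a marker of olfactory neurons, which was well above background in 2 controls and in 0 exposed replicates. In the main processing it was at least 1.31-fold lower (adjusted p = 0.000125). The heat shock list had 6 of 21 members up and 0 down, and 11 up adjusted over the list alone (camera adjusted p = 5.52e-07; adjusted p = 0.245 with an estimated correlation). The liver list had 1 up and 12 down, and 1 and 15 adjusted over the list alone (camera adjusted p = 3.69e-06; adjusted p = 0.133 with an estimated correlation), with c9 at -1.13 ± 0.16. The bone and matrix list had 2 up and 9 down, and 2 and 12 adjusted over the list alone (camera adjusted p = 0.000131; adjusted p = 0.133 with an estimated correlation). Cell cycle genes were lower as well (0 up, 9 down; 0 and 10 adjusted over the list alone; camera adjusted p = 0.00264; adjusted p = 0.518 with an estimated correlation). So were the exocrine pancreas list (0 up, 4 down; 0 and 6 adjusted over the list alone; camera adjusted p = 0.00824) and the epidermis list (0 up, 3 down; 0 and 9 adjusted over the list alone; camera adjusted p = 0.0348). With an estimated correlation these 2 lists had an adjusted p of 0.572 and 0.518. The pancreas list did not pass without control replicate 2 (adjusted p = 0.101), and the epidermis list not without exposed replicate 1 (adjusted p = 0.104) or control replicate 3 (adjusted p = 0.0542) or 4 (adjusted p = 0.0652). The values of fos at 0.74 ± 0.50 (adjusted p = 0.445), hmox1 at 0.34 ± 0.19 (adjusted p = 0.317) and cyp1a at -0.31 ± 0.24 (adjusted p = 0.537, n = 3 controls) did not pass. Without exposed replicate 3 cyp1a was at -0.14.

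A total of 2393 probes were called at 3.8 mg/L, 1140 up and 1253 down, and 258 of them changed at least 2-fold. Quantile normalisation called 1431 up and 1067 down, and the values the authors deposited 1244 up and 1126 down. With slide as a block 2176 were called, and on the 3 slides that held both groups the heat shock medians were 0.23, 0.04 and 1.07. The 0.04 was measured against control replicate 4, which had the highest level of this list among the controls. Normexp correction put the median of all probes at 0.11, called 783 and turned omp to 0.04, and without replicate 4 of this group 1510 were called.

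At 1.9 mg/L 1 named gene rose, the transcription factor gene cebpd, at 0.87 ± 0.13 (adjusted p = 0.01). The 3 that fell were ehhadh at -0.62 ± 0.11 (adjusted p = 0.0342), mao, the monoamine oxidase gene, at -0.59 ± 0.11 (adjusted p = 0.0427), and cyb5a, the electron carrier cytochrome b5, at -0.53 ± 0.09 (adjusted p = 0.0277). The next smallest p-values belonged to agt at 1.15 (adjusted p = 0.0522), ctsl1a at 0.46 and vil1l at -0.68 (adjusted p = 0.0724 for both), which did not pass. Ribosomal protein genes were higher as a list, with a median of 0.11 and 0 of 63 members called by themselves, 2 adjusted over the list alone (camera adjusted p = 1.56e-06; adjusted p = 0.745 with an estimated correlation). Activity-induced early genes were also higher as a list (0 members called; camera adjusted p = 0.021; adjusted p = 0.745 with an estimated correlation). Lists of xenobiotic metabolism (camera adjusted p = 0.0284; adjusted p = 0.745 with an estimated correlation) and cell cycle (camera adjusted p = 0.021; adjusted p = 0.745 with an estimated correlation) were lower, again with 0 members called. Without exposed replicate 4 none of these 4 lists passed, at a camera adjusted p of 0.0875 (ribosomal), 0.395 (early genes), 0.0875 (xenobiotic) and 0.0977 (cell cycle). That took the mean of the early genes from 0.242 to 0.127 and of the ribosomal list from 0.117 to 0.0563, which was 0.199 without exposed replicate 2. Early genes and xenobiotic metabolism also did not pass without control replicate 1 (adjusted p = 0.088 for both), 2 (0.0592 and 0.0768) or 4 (0.0573 and 0.077). Without exposed replicate 1 xenobiotic metabolism and cell cycle had an adjusted p of 0.0879, and cell cycle 0.088 without control replicate 1. There were 22 called probes, 11 up and 11 down. The slide block gave 4 probes and normexp correction 14 (2 up, 12 down), and with either of them 0 of the 4 named genes passed. The slide block put the adjusted p of cebpd at 0.0887 and that of cyb5a at 0.138. The count was 4 without replicate 2 or 4 of this group, 13 without its replicate 1, 8 without control replicate 1 and 11 without control replicate 3. The gene cebpd lost its call without exposed replicate 2 (0.80, adjusted p = 0.0563) or 4 (0.82, adjusted p = 0.0646). The call of ehhadh ended without exposed replicate 1, 2, 3 or 4 (adjusted p = 0.0533, 0.142, 0.0925 and 0.108) or control replicate 1, 2 or 3 (adjusted p = 0.0909, 0.0585 and 0.154). That of mao ended without exposed replicate 1, 2, 3 or 4 (adjusted p = 0.0839, 0.142, 0.105 and 0.122) or control replicate 1, 2 or 4 (adjusted p = 0.172, 0.11 and 0.0902). For cyb5a it ended without exposed replicate 1, 2 or 4 (adjusted p = 0.102, 0.0916 and 0.0901) or control replicate 1, 2 or 4 (adjusted p = 0.0801, 0.0857 and 0.052).

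At 0.9 mg/L upf1, a helicase of nonsense-mediated mRNA decay, rose by 0.56 ± 0.10 (adjusted p = 0.0425, n = 3 exposed), and the dipeptidase gene cndp2 fell by 0.78 ± 0.14 (adjusted p = 0.0466). Not passing were cyb5a at -0.50 ± 0.10 (adjusted p = 0.129), the steroid dehydrogenase gene hsd11b3 at -0.72 ± 0.15 (adjusted p = 0.13) and cad, of pyrimidine synthesis, at 0.47 ± 0.10 (adjusted p = 0.13). The ribosomal protein list was lower here, with a median of -0.10 (camera adjusted p = 0.01; adjusted p = 0.768 with an estimated correlation). So was the cell cycle list, with a median of -0.20 (camera adjusted p = 0.00114; adjusted p = 0.677 with an estimated correlation). The epidermis list (camera adjusted p = 0.00543; adjusted p = 0.677 with an estimated correlation) and the respiratory chain list (camera adjusted p = 0.0145; adjusted p = 0.768 with an estimated correlation) were lower too. By an adjusted p limma called 0 members of these 4 lists. With slide as a block the liver list (camera adjusted p = 0.0137) and the exocrine pancreas list (camera adjusted p = 0.0188) also passed as lower. Without the block each had a camera adjusted p of 0.192, and 0.768 with an estimated correlation. The ribosomal list did not pass without exposed replicate 1 (adjusted p = 0.0635) or control replicate 2 (mean -0.0639 against -0.0969, adjusted p = 0.412). The respiratory chain list did not pass without exposed replicate 3 (adjusted p = 0.142), and its mean of -0.11 was -0.0679 without control replicate 3. In total 9 probes were called, 3 up and 6 down, against 3980 at an unadjusted p under 0.05. Quantile normalisation gave 9 (4 up, 5 down), normexp correction 3 (0 up, 3 down), the values the authors deposited 2 (1 up, 1 down) and the slide block 0. The count was also 0 without any one of the 3 exposed replicates or without control replicate 1, 3 or 4, and cndp2 lost its call without control replicate 2 as well. With normexp correction upf1 (adjusted p = 0.363) and cndp2 (adjusted p = 0.0735) did not pass.

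A further question was which transcripts follow the concentration. Slopes are log2 units per unit of log2(mg/L + 1), over 23 samples, or fewer where a sample had no usable spot. That of fkbp5 lacked 15 mg/L replicates 2 and 4 and 7.5 mg/L replicate 4, and that of cyp1a lacked control replicate 1. Among the steepest rises were hsp47 at 0.88 ± 0.08 (adjusted p = 3.69e-08) and fkbp5 at 0.82 ± 0.11 (adjusted p = 4.86e-06). They were followed by dnaja1l at 0.58 ± 0.05 (adjusted p = 3.02e-08), ndrg1l at 0.52 ± 0.04 (adjusted p = 6.59e-10) and fos at 0.49 ± 0.11 (adjusted p = 0.00136). The steepest falls were cyp2j28 at -0.71 ± 0.06 (adjusted p = 1.08e-08) and per4 at -0.55 ± 0.04 (adjusted p = 5.15e-09), before nr1d1 at -0.50 ± 0.06 (adjusted p = 7.86e-07), ugt1ab at -0.49 ± 0.06 (adjusted p = 5.14e-07) and asah2 at -0.46 ± 0.05 (adjusted p = 3.02e-07). Along the series hmox1 rose, at 0.19 ± 0.04 (adjusted p = 0.00188), while cyp1a at -0.11 ± 0.05 (adjusted p = 0.159) did not pass. In all 6882 probes were called, 3484 up and 3398 down, and 5226 with slide as a block (2379 up, 2847 down). Without the 15 mg/L samples 3055 were called, of which 2884 were among the 6882.

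**Figure D3:**
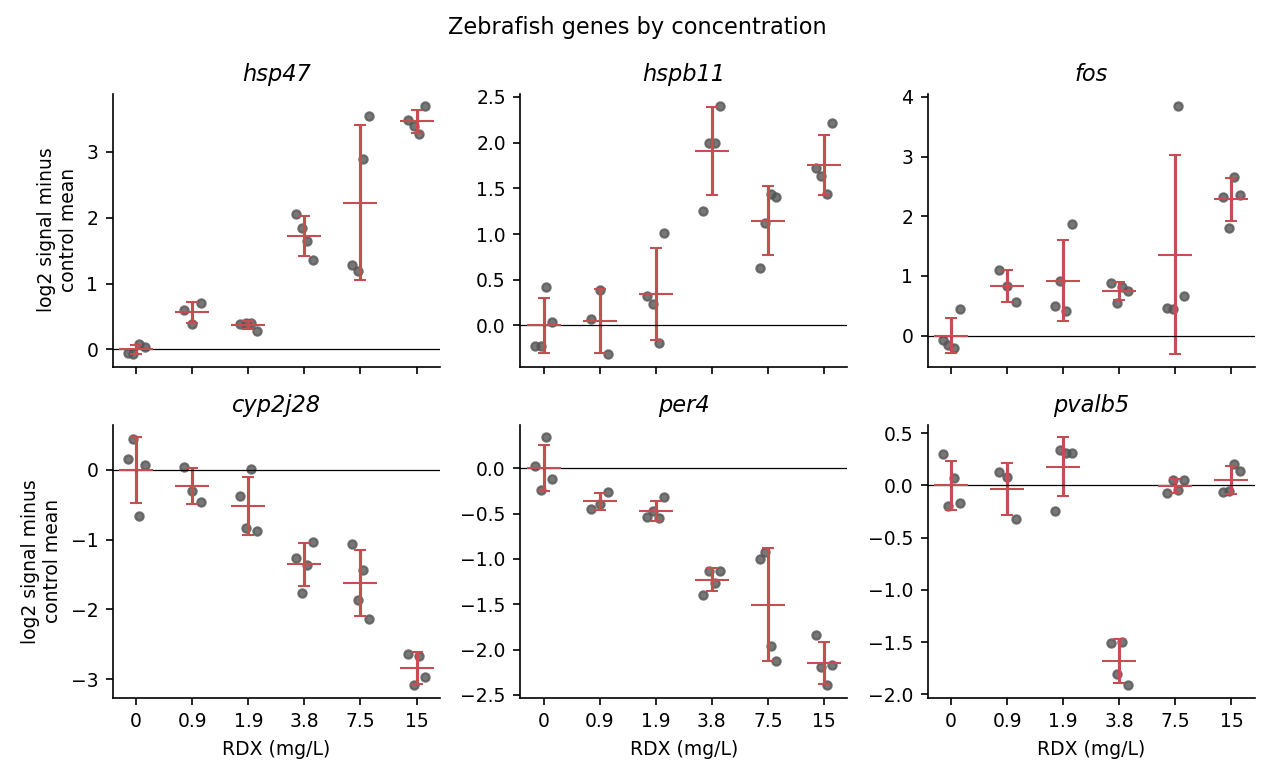
Log2 signal minus the control mean (y axis) of single zebrafish genes at each RDX concentration (x axis, mg/L); points are replicates and bars are means with SD. At 15 mg/L hsp47 averaged 3.46 and cyp2j28 -2.84 against the control.

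Concentrations were also compared with each other. From 7.5 to 15 mg/L 114 probes differed, from 3.8 to 15 mg/L 540, and from 3.8 to 7.5 mg/L 68. These contrasts were fitted without a slide block. No slide held arrays of both 3.8 and 7.5 mg/L, so differences between these concentrations cannot be separated from slide. The fall of cyp2j28 was larger at 15 than at 7.5 mg/L, by -1.22 ± 0.24 (adjusted p = 0.0305). The rise of hsp47 was larger at 15 than at 3.8 mg/L, by 1.74 ± 0.33 (adjusted p = 0.00614), whereas its difference from 7.5 mg/L, 1.24 ± 0.33, did not pass (adjusted p = 0.104). Early genes as a list were higher at 15 than at 7.5 mg/L (camera adjusted p = 8.39e-08; adjusted p = 0.227 with an estimated correlation). The heat shock list was lower at 7.5 than at 3.8 mg/L (camera adjusted p = 2.24e-07; adjusted p = 0.434 with an estimated correlation). It was higher at 15 than at 7.5 mg/L (camera adjusted p = 0.000107; adjusted p = 0.305 with an estimated correlation). Of the probes called at 7.5 and at 15 mg/L, 1119 were up in both and 1037 down in both. Independent lists of these sizes would share 133.9 and 116, unchanged groups simulated against the same controls shared 0, and with the controls split between the comparisons 493.5 and 477.3 were shared on average. The covariance of the changes was 0.107, against 0.0295 for simulated unchanged groups. The simulated groups held independent noise without slide differences, so an overlap near 0 among them follows by construction. All 7.5 mg/L arrays, and 15 mg/L replicates 1, 3 and 4, were on slides 3 and 5, which held no controls. Splitting the controls does not remove a slide difference that these groups share.

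In fathead minnow the array gives contig numbers and no gene symbols, so probes are named by their identifiers. At 15 mg/L 24 of 12335 probes were called, 3 up and 21 down, with 2 and 16 of them at least 2-fold (n = 4 exposed, 3 controls). The largest rises were UF_Ppr_AF_102810 at 1.28 ± 0.17 (adjusted p = 0.00221) and UF_Ppr_AF_105140 at 1.16 ± 0.19 (adjusted p = 0.0118). The largest falls were UF_Ppr_AF_105294 at -1.62 ± 0.20 (adjusted p = 0.00221) and UF_Ppr_AF_100819 at -1.56 ± 0.26 (adjusted p = 0.0118). The count was 97 with slide as a block (22 of the 24 among them), 47 with quantile normalisation (16 up, 31 down), 5 without control replicate 1, 7 without control replicate 2 and 69 without replicate 1 of this group. UF_Ppr_AF_105140 lost its call without control replicate 2 (adjusted p = 0.0666) or 3 (adjusted p = 0.0583), and UF_Ppr_AF_100819 without control replicate 1 (adjusted p = 0.121) or 2 (adjusted p = 0.115).

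At 7.5 mg/L 7 fathead minnow probes were called, 4 up and 3 down. The largest rises were UF_Ppr_AF_112953 at 0.78 ± 0.14 (adjusted p = 0.046) and UF_Ppr_AF_115802 at 0.71 ± 0.11 (adjusted p = 0.0247). Falls were led by UF_Ppr_AF_109367 at -1.05 ± 0.17 (adjusted p = 0.0257) and UF_Ppr_AF_106113 at -0.91 ± 0.15 (adjusted p = 0.0309). Slide as a block gave 14, of which 3 were among the 7, and ended the calls of UF_Ppr_AF_112953 (adjusted p = 0.0587), UF_Ppr_AF_115802 (adjusted p = 0.0858) and UF_Ppr_AF_106113 (adjusted p = 0.0727). The count was 331 with quantile normalisation (257 up, 74 down), 180 without slide 2 (16 up, 164 down), 6 with the values the authors deposited (2 up, 4 down) and 0 with normexp correction, with the median of all probes at 0.11 here and at 0.16 at 15 mg/L. Without any one of the 3 controls, or without replicate 1 or 3 of this group, limma called 0 by an adjusted p, without its replicate 2 it called 3 and without its replicate 4 it called 160.

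At 0.9 and 1.9 mg/L limma called 0 fathead minnow probes, with 1029 and 1786 at an unadjusted p under 0.05. Slide as a block gave 0 and 5, the fit of all arrays with run as a covariate 3 and 23, and the values the authors deposited 0 and 7. The trend over concentration called 112 probes, 42 up and 70 down. The steepest were UF_Ppr_AF_118772 at 0.51 ± 0.12 (adjusted p = 0.046) and UF_Ppr_AF_101844 at 0.33 ± 0.07 (adjusted p = 0.0289) upward. Downward they were UF_Ppr_AF_107917 at -0.51 ± 0.10 (adjusted p = 0.0289) and UF_Ppr_AF_110746 at -0.42 ± 0.09 (adjusted p = 0.0353). With slide as a block 53 were called, 35 of them among the 112 and none of the 4 named (UF_Ppr_AF_101844 at 0.16 and UF_Ppr_AF_110746 at -0.27). The count was 266 with quantile normalisation (176 up, 90 down), 319 without slide 2 (42 up, 277 down) and 5 without the 15 mg/L samples. Without control replicate 2 UF_Ppr_AF_118772 lost its call (0.51, adjusted p = 0.0703).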

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

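The mislabelling test along the axis from control to 15 mg/L and the counts over other splits were set before their results were seen; the slide tests, the tests of the first component and of fathead minnow control replicate 2, the 3 further axes, the rule for differences between concentrations and the extension of single-sample tests to list members were chosen afterwards.

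Within the zebrafish 7.5 mg/L group, replicates 3 and 4 had higher heat shock levels than replicates 1 and 2. Other exposed groups were spread as well. Levels ran from -0.0012 to 0.633 at 7.5 mg/L, from 0.305 to 0.949 at 3.8 mg/L and from 0.369 to 0.809 at 15 mg/L. A difference between slides is argued against for replicate 3 only, which lay 0.602 (log2) above the mean of replicates 1 and 2 on the same slide, while the 4 controls spanned 0.197; replicate 4 was on another slide, so for it this stays open. A mislabelled 15 mg/L sample is not excluded. Replicates 3 and 4 lay at 0.608 and 0.751 on an axis from control (0) to 15 mg/L (1), and the lowest 15 mg/L sample lay at 0.572. The axis left out the brightest probe of each gene of the heat shock list, so further probes of these genes could stay on it. That axis separates the groups poorly, because replicate 2 lay at 0.645 and the 3.8 mg/L samples from 0.46 to 0.614, and on the 3 further axes replicate 3 lay at 0.592, 0.575 and 0.524 and replicate 4 at 0.746, 0.632 and 0.581, against 0.663, 0.699 and 0.646 for the lowest 15 mg/L sample. Replicate 3 shared slide 3 with 15 mg/L replicate 1, and replicate 4 shared slide 5 with 15 mg/L replicates 3 and 4. Their positions on these axes therefore cannot be separated from slide. A stronger response of these beakers may also explain the pattern, so it stays open.

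The first principal component of the zebrafish arrays, with 23.2% of the variance, separated slides. Slide took 0.942 of its variance within concentrations (permutation p = 0.00025), and concentration took 0.303 of its variance, which argues against concentration as its main source. The second component, with 12.9%, had a share of 0.806 for concentration. Differences in labelling, hybridisation or scanning between slides are a candidate explanation, and the beakers on each slide differ as well, which was not tested.

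Among the fathead minnow arrays those of control replicate 2 scored highest on the first component in both runs (64.73 and 51.68), but the 420 run array of 0.9 mg/L replicate 1 lay beside them at 51.3. A fault of a single array is argued against, because its deviations correlated by 0.806 between its 2 runs, against at most 0.753 for any other replicate. Its share of spots well above background was 95.3% in the 420 run, and the next highest, 91.3%, was that same 0.9 mg/L array, whose deviations correlated by 0.654 with control replicate 2 in the 440 run and by 0.211 with its own replicate (compared after the data were seen). RNA quality or tissue composition of the control pool may account for its place, and a mix-up or carry-over of RNA for the 0.9 mg/L array was not tested. The tables do not separate these; no biological explanation from the design applies within a control group.

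Other splits of the same samples, 35 per comparison, show whether chance can be excluded. They leave slide out of account, so they cannot exclude an uneven spread of the groups over slides. Slide aside, chance can be excluded in zebrafish at 3.8 mg/L (2393 probes, highest other split 5) and 15 mg/L (6835 and 782). There 1 split, the real one, gave as many, and 2176 and 3069 probes were called with slide as a block. Slide aside, it also can for the trend (6882 and 76, 1 of 100 orders), where the slide block called 5226. At 7.5 mg/L (2355 and 89) chance stays open, although only the real split gave as many. No slide held both groups there, and 158 were called with slide as a block. At 1.9 mg/L (22 probes, highest other split 1) it stays open. There 4 were called with slide as a fixed block or without exposed replicate 2 or 4, and 3 with only the 2 groups compared. At 0.9 mg/L (9 probes, highest other split 0) it stays open, because 0 were called with slide as a fixed block, with the replicate block and without any one of 6 of the 7 replicates. It cannot for the gene lists at 15 mg/L, where 8 of 35 splits gave 8 or more lists and the highest gave 12. In fathead minnow it stays open for the trend (112 and 1, 1 of 100 orders), since the orders leave slide out of account. With slide as a block 53 were called, and without the 15 mg/L samples 5. At 7.5 mg/L (7 and 1) it stays open, because 0 were called with the replicate block, with normexp correction and without any one of 5 of the 7 replicates. It cannot at 15 mg/L, where 2 of 35 splits gave 24 or more probes. The highest, 26, set apart the 15 mg/L replicates 2, 3 and 4, which all have arrays on slide 2; with slide as a block 97 probes were called and without the arrays of slide 2 there were 51. At 0.9 and 1.9 mg/L limma called 0 (1029 and 1786 at an unadjusted p under 0.05), so all 35 splits (highest 12 and 1) reach that by construction and say nothing about chance.

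Single samples far from the other 3 of their group were found in 15 of 265 tests, and chance gives about 1 in 20. In zebrafish control replicate 3 these were ehhadh at 0.3265 (others -0.0164 to 0.0268), slc1a2 at 5.687 (5.26 to 5.272), cat at 1.251 (1.708 to 1.762), pvalb4 at 6.604 (5.988 to 6.041), smyhc1 at 4.599 (5.248 to 5.303), grk7b at -1.256 (-1.387 to -1.373) and atp5f1 at 6.281 (5.998 to 6.005). At 15 mg/L they were, in replicate 3, atp1a3b at 0.4541 (0.8893 to 0.9567), mylz3 at 3.428 (2.909 to 2.932), ehhadh at -0.9673 (-1.266 to -1.215) and the exocrine pancreas list at -0.377 (-0.644 to -0.621). The rest were atp1a3a in replicate 4 at 0.9521 (0.6218 to 0.6718), elovl2 in replicate 1 at -1.188 (-1.791 to -1.717), the immune list in replicate 2 at -0.36 (-0.103 to -0.0548), and the heat shock list in control replicate 4 at 0.137 (-0.06 to -0.0375).

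Differences between concentrations in direct contrasts were found for pvalb5, higher by 1.7358 at 15 than at 3.8 mg/L and by 1.6774 at 7.5 than at 3.8 mg/L, and for omp, with fitted differences of 2.0526 and 2.0801. Those of omp do not measure a size, since it was well above background in 0 replicates of 3.8 mg/L (2 controls), and with normexp correction its change there turned to 0.0446. For both genes the contrast of 7.5 with 3.8 mg/L cannot be separated from slide, since no slide held both groups.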

How the results depend on the processing

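Slide as a random block, slide and replicate blocks for the lists, leaving out slide 2, leaving out 1 replicate for the lists, and the fathead minnow trend without control replicate 2 were chosen after the data were seen; all other alternatives were planned.

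Zebrafish counts were 9, 22, 2393, 2355 and 6835 probes from 0.9 to 15 mg/L and 6882 for the trend. Normexp correction gave 3, 14, 783, 823 and 2807, and a fit of only the groups compared 0, 3, 1148, 756 and 4436. Slide as a fixed block gave 0 at 0.9, 4 at 1.9, 158 at 7.5 and 3069 at 15 mg/L. At 0.9 mg/L no filter on dim probes gave 5, the values of the authors 2, the replicate block 0 and slide as a random block 1, while at 1.9 mg/L the authors' values gave 14. Counts within 1.5 times of the reported ones are not listed. Leaving out 1 replicate gave 0 to 13, 4 to 31, 1510 to 2166, 1468 to 2067 and 5498 to 6570. The trend without the highest concentration called 3055. Of the lists at 15 mg/L, 8 passed, 0 with an estimated correlation and 15 with fry (3 up, 12 down), and 7 to 8 without 1 replicate.

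Fathead minnow counts were 0, 0, 7 and 24 probes at 0.9, 1.9, 7.5 and 15 mg/L and 112 for the trend. The fit of all arrays with run as a covariate gave 3, 23, 267 and 216, the 440 run alone 1, 1, 82 and 2, and the 420 run alone 6 at 1.9 and 0 at 7.5 mg/L. Slide as a block gave 5, 14 and 97 from 1.9 mg/L up and 53 for the trend, and the authors' values 7 at 1.9 mg/L. Quantile normalisation gave 331, 47 and 266 at 7.5 mg/L, 15 mg/L and for the trend, leaving out slide 2 gave 180 (16 up, 164 down), 51 and 319 (42 up, 277 down), and the replicate block 0, 15 and 34. At 7.5 mg/L normexp correction gave 0 and the fit of only 2 groups 0, and at 15 mg/L the latter gave 2. The trend was 437 over mg/L, 70 without the filter on dim probes and 5 without the highest concentration, and 93 without control replicate 2. Leaving out 1 replicate gave 0 at 0.9 and 1.9 mg/L, 0 to 160 at 7.5 mg/L and 5 to 69 at 15 mg/L. The causes of these differences were not tested.

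With normexp correction omp at 3.8 mg/L turned to 0.0446. The value of hmox1 at 1.9 mg/L turned negative with normexp correction (-0.0238), the authors' values (-0.0096), and without control replicate 2 (-0.0783) or 4 (-0.0535) or exposed replicate 2 (-0.0446) or 4 (-0.142), the range without 1 replicate being -0.142 to 0.1451. Of the planned values of single genes and lists 2059 kept direction and side of the threshold, 253 lost and 10 gained a call and 7 turned direction, and of the added ones 371, 7, 2 and 0. Signal over background limits the falls of dim probes, whose size depends on the background correction.

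Replicate numbers were not taken to pair the samples. Same-number samples correlated by 0.0647 on average in zebrafish (lowest -0.322), against -0.022 for other pairs. Of 23 zebrafish samples 10 matched a sample of their own number best, so a part shared by number stays open. In fathead minnow the means were -0.0242 (lowest -0.489) and 0.00793, with 3 of 19 matching best. The replicate block changed zebrafish counts at 15 mg/L to 6807 and at 0.9 mg/L from 9 to 0. Fathead minnow counts went from 7 to 0 at 7.5 mg/L and from 24 to 15 at 15 mg/L. The planned fathead minnow gene lists and the difference between species were not run, since no gene names are at hand for its probes.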

Other observations

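The transcript LOC560210 was chosen after its values were seen, and the lists of both hypotheses were written before they were tested.

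In zebrafish at 15 mg/L an Hsp70-like transcript without a gene symbol, LOC560210, rose more than any gene named by the rule, by 4.19 ± 0.54 (adjusted p = 8.99e-06). It stood at 1.93 at 7.5 mg/L (adjusted p = 0.0313) and at 1.70 at 3.8 mg/L (adjusted p = 0.057).

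The rise of fkbp5 may reflect glucocorticoid signalling, since this gene is a target of the receptor. A list of 11 other responsive genes gave no such shift, with an adjusted p of 0.617 with an estimated correlation and 0.455 with the preset one. Of its members 5 rose and 3 fell, among them hsd11b2 at 1.47 and cebpb at 1.17 upward, and mao at -1.19 and hsd11b3 at -1.35 downward.

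The falls of per4 and nr1d1 could belong to a shift of the circadian clock. A list of 10 other clock genes had a median of -0.447, with 2 up and 5 down. Its camera adjusted p was 0.0827 with an estimated correlation, against 0.0138 with the preset one. The members tef, cry3 and bhlhb3l were at -1.14, -1.26 and -1.07, and cry2b at 1.08. The test set beforehand, a common fall, was therefore not met. It cannot decide about a shift that moves members of the list in opposite directions. The hour at which each beaker was sampled is not given in the sources used here.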
